A study of Danio rerio with 2 samples.

How the data were processed

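Whole embryos were pooled per group, and 1 poly-A-selected library was made for untreated embryos and 1 for embryos exposed to 20 µM cyproconazole, per the labels' protocols. The submitters' processing notes name the genome build GRCz10 and the tools TopHat2 2.0.4, SAMtools, Picard 1.29, HTSeq 0.6.1 and Cufflinks 2.1.1, without a role or an order for any of them. The gene annotation, the strand setting of the counting and the handling of reads that match several genes are not given in the sources used here, so reads shared by paralogs or by overlapping and antisense genes could not be told apart. Gene positions were not used here.

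The authors deposited a single table with 1 row per gene. It holds an FPKM value (fragments per kilobase of transcript, scaled to depth) for each library, per the file headers. It also holds a mean of normalized counts over both libraries per gene, a signal that the authors divided by size factors. A log2 ratio with its standard error in log2 units and an unadjusted p-value come from the authors' own comparison, per the file headers, whose column names are those of DESeq2. These deposited log2 ratios are shrunken towards 0, with a range of -0.38 to 0.37 in the authors' deposited table, and were not used as effect sizes. Of 23809 genes in the authors' deposited table, 110 had an unadjusted p-value under 0.05 and the smallest was 0.0222. These p-values rest on 1 library per group and were not used as tests.

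Of the gene identifiers, 21800 matched a current symbol in the reference table. The table gives no symbol for 3744 genes, and 13 symbols had been turned into dates and were replaced by the current symbol. An FPKM of 0 is not always the absence of a transcript: 555 genes are listed at 0 in at least 1 library, 12 of them with at least 50 reads, among them the muscle myosin gene myhz1.1 with 87539 and 89128 reads. Such genes were left out of FPKM comparisons. One of them is the cartilage collagen gene col9a2, named after its value was seen and listed at 0 in the control, with a read ratio of 0.606 (0.591 to 0.621).

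The planned comparison assumed counts. Because the per-library columns are FPKM, the planned fallback was used: the difference of log2(FPKM + 1) between libraries, a scale that understates the change of low genes, with no test. Whole reads were then recovered as an addition chosen after the data were seen. All 23809 mean counts are whole multiples of 1 step within 0.01 of that step (largest deviation 0.0059), and the steps of the control and the treated library are in the ratio 68 to 59. Each mean count therefore fits a limited set of pairs of whole reads, with 1 pair for 7180 genes. The number of pairs grows with the mean count, so for abundant genes the choice rests mainly on the model below. For each pair, the dispersion that gives the deposited log2 ratio in a negative binomial model with a zero-centred normal prior was solved, and the pair whose standard error matched the deposited one within 1e-05 was kept if the next pair missed by at least 10 times more. This gave whole reads for 23790 genes (99.9%), and the 19 others hold 0.045% of the summed mean counts. Over the 18621 genes with both values, the FPKM and read log2 ratios had a correlation of 0.86 across genes, which are not independent replicates, and 333 genes differed by more than 0.5.

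Read ratios were scaled by a trimmed mean of M values, with 30% of log ratios and 5% of mean expression trimmed, computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The offset from total reads was 0.004 on the log2 scale. Intervals are exact conditional binomial (Clopper-Pearson) intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. Genes needed at least 50 reads over both libraries. The 10 most abundant genes took 8.37% of reads in the control and 8.70% in the cyproconazole library.

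Before the data were examined, 42 gene lists and 22 gene families were fixed, as were the rules of size, most of the alternatives and the rule for named genes. A list was described by its median, by its members past 1.5-fold on the FPKM + 1 scale, and by the percentile of its median among 10000 random lists of the same size matched in 20 bins of mean expression. This percentile describes these libraries and is not a test of the treatment. Of the 64 lists and families, 61 had at least 3 measured genes. The named genes are the 12 highest and the 12 lowest by the bound of the counting interval nearest to 1, up to 4 members of each list described, and 17 genes always named. Of the 17, sp7 and bglap were not analysed here. The highest, the lowest and the list members were picked among genes with a conventional symbol, so clone-based and unnamed genes were not ranked. Other genes are said to be named after their values were seen. The alternatives were other scalings, read minimums, thresholds and added values, and the summed reads of a list. Those chosen after the data were seen are the trimmed mean of M values for recovered reads, 0.1 added to each FPKM, FPKM centred on the median gene, and FPKM without a minimum of reads or with at least 1 FPKM. The trimmed mean of M values had been the planned main scale for counts. The other scalings were planned for counts too, so each was run on recovered reads, whose use was chosen after the data were seen.

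The recovery was tested on simulated data. Reads were drawn for 23400 genes from the recovered means of this comparison, with 200 genes changed 2.5-fold, and turned into a table of the same columns. Whole reads were recovered for 99.97% of the simulated genes, and all recovered genes had exactly the simulated reads. The simulated log2 ratios and standard errors came from the same model, prior and dispersions that the recovery assumes. The simulation therefore checks the inversion and not whether the deposited table follows that model. By read ratio, 98% of genes simulated 2.5-fold higher and 97% of genes simulated 2.5-fold lower passed the 2-fold rule. So did 8 of 18413 unchanged genes. The draws held counting error and no difference between pools of embryos. These shares are therefore not the sensitivity or the false-call rate of the 2-fold counts reported on the FPKM scale. The counting intervals held the simulated ratio for 95.6% of genes, and of 40 random lists 3 lay outside the central 95%. Figures were drawn with matplotlib 3.10.9.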

Results

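Poly-A RNA of whole zebrafish embryos was sequenced at 3 days post fertilization in 2 libraries, 1 from untreated embryos and 1 from embryos kept in 20 µM cyproconazole, a triazole fungicide, from 4 hours post fertilization onwards. Each library came from a pool of 40 embryos that were heterozygous for a mutant allele of mitfa, a regulator of pigment cells. The deposited table holds 23809 genes with an FPKM value per library. The whole reads behind the table, recovered from its other columns, sum to 18067935 in genes for the control library and 20726375 for the cyproconazole library. With 1 library per group no difference below has a replicate check, so each ratio compares these 2 libraries and not the conditions in general. The interval beside a read ratio is a 95% exact binomial interval that covers counting error only.

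The comparison addresses which genes, among them those of fat-cell and bone-cell formation named in the study's title, differ in embryos exposed to cyproconazole. Among genes with a conventional symbol, the highest ratio by counting interval belonged to cyp26a1 (ENSDARG00000033999), an enzyme that breaks down retinoic acid. It had 15.2 FPKM in the control and 147 FPKM in the cyproconazole library, a read ratio of 9.56 (8.70 to 10.5). Several of the lowest among genes with a conventional symbol belonged to genes of cartilage and extracellular matrix, among them clec3a at a read ratio of 0.079 (0.0307 to 0.171), the procollagen-processing enhancer pcolceb at 0.113 (0.0796 to 0.157), and the abundant cartilage protein matn1, which had 253 FPKM in the control and 50.6 FPKM in the cyproconazole library (0.195, 0.187 to 0.204). Most genes lay close to a ratio of 1. Of 18640 genes compared on the log2(FPKM + 1) scale, 96.7% were within 1.5-fold, 50 were at least 2-fold higher and 83 at least 2-fold lower in the cyproconazole library. By reads, 27 of the 50 and 70 of the 83 were also at least 2-fold apart in the same direction, and 34 and 77 had a counting interval that lay off 1 in that direction.

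Among genes with a conventional symbol, the 12 with the highest ratio by their counting interval were cyp26a1, sdr42e2, dhrs3a, cyp26b1, hoxb5b, dhrs3b, gstp2, hoxb6b, hbbe3, hoxb5a, nr0b2a and duox. Among those outside retinoic acid metabolism, sdr42e2 had a read ratio of 6.24 (4.54 to 8.76), the embryonic globin hbbe3 3.77 (2.52 to 5.81), the dual oxidase duox 3.45 (2.41 to 5.07) and the nuclear receptor nr0b2a 2.83 (2.41 to 3.33). The glutathione S-transferase gstp2 had a read ratio of 3.59 (2.71 to 4.82) but 31.1 and 39.7 FPKM, and its value is uncertain because reads can be shared with a close paralog, as they can for hbbe3. The 12 lowest with a conventional symbol were epd, pcolceb, clec3a, tnxba, matn1, foxe1, acana, mia, itih6, phka1b, thbs2 and agxtb. The ependymin gene epd had a read ratio of 0.111 (0.0822 to 0.146), the tenascin gene tnxba 0.161 (0.143 to 0.181), the transcription factor gene foxe1 0.109 (0.0523 to 0.204) and the thrombospondin gene thbs2 0.187 (0.137 to 0.25). The liver enzyme gene agxtb, an alanine-glyoxylate aminotransferase, had 27.0 and 7.16 FPKM and a read ratio of 0.257 (0.221 to 0.297).

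**Figure D1:**
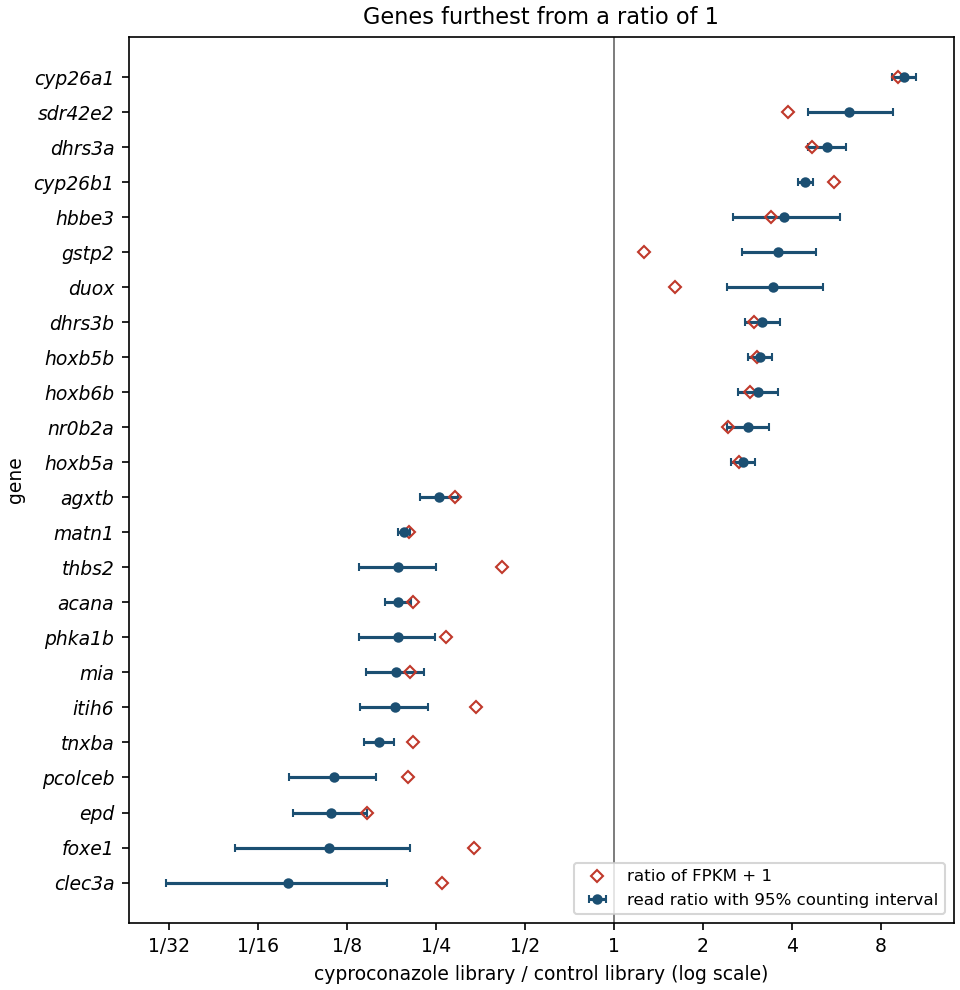
The 12 genes with the highest and the 12 with the lowest ratio of the cyproconazole library to the control library, among genes with a conventional symbol, on a log scale. Filled circles are read ratios with 95% counting intervals and open diamonds are ratios of FPKM + 1; cyp26a1 stands at 9.56 and clec3a at 0.079 by reads, and low genes such as foxe1 lie nearer to 1 by FPKM + 1.

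Genes that respond to or metabolize retinoic acid were higher as a group. Of the 29 measured genes of this list, 9 were at least 1.5-fold higher in the cyproconazole library and 0 at least 1.5-fold lower, and the list's median log2(FPKM + 1) difference of 0.24 was at percentile 100 of 10000 random lists matched on expression. Besides cyp26a1, the retinoic acid hydroxylase cyp26b1 had 17.9 and 103 FPKM (read ratio 4.43, 4.17 to 4.70), and the retinaldehyde reductase genes dhrs3a and dhrs3b had read ratios of 5.24 (4.52 to 6.10) and 3.17 (2.77 to 3.64). The Hox genes, which set position along the body axis, had a median difference of 0.27 over 47 measured genes (percentile 100), with 15 at least 1.5-fold higher and 1 at least 1.5-fold lower. The Hox and retinoic acid lists overlap, since hoxb5b is on both. The read ratio was 3.12 (2.84 to 3.42) for hoxb5b, 3.06 (2.63 to 3.57) for hoxb6b, 2.73 (2.49 to 3.00) for hoxb5a and 2.53 (2.25 to 2.85) for hoxc1a. When split by paralog group, a split chosen after the values were seen, the 25 genes of groups 1 to 8 had a median difference of 0.77 and held all 15 of the higher genes, and the 22 genes of groups 9 to 13 had a median of 0.08. Of these, the 16 genes of groups 9 to 12 had a median of 0.14, with 14 of them above 0. The 6 genes of group 13 had a median of -0.37, with 5 of them below 0. Exceptions in groups 1 to 8 were hoxa2b and hoxc6b, with read ratios of 0.64 (0.51 to 0.81) and 0.65 (0.50 to 0.84). The lowest Hox genes by reads were hoxb13a at 0.33 (0.23 to 0.47), hoxa13a at 0.545 (0.339 to 0.865) and hoxc13a at 0.615 (0.462 to 0.816). These 5 genes were named after their values were seen.

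**Figure D2:**
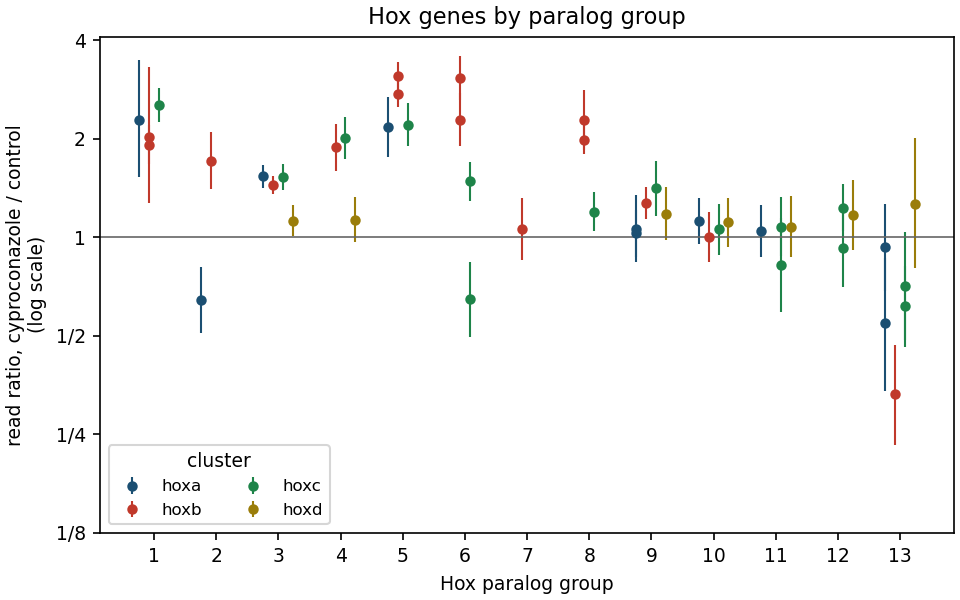
Read ratio of each measured Hox gene (cyproconazole over control, log scale) against its paralog group, from 1 at the anterior end of the clusters to 13, coloured by cluster; bars are 95% counting intervals. Genes of groups 1 to 8 lie mostly above 1, with hoxa2b and hoxc6b below, 14 of the 16 genes of groups 9 to 12 lie above 1, with ratios up to 1.41, and 5 of the 6 genes of group 13 lie below 1, with hoxb13a lowest at 0.33.

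The adipogenic list, genes of fat-cell formation and lipid storage, had a median difference of 0.00 over 32 measured genes, at percentile 38.6 of the random lists. The RNA came from whole embryos, so the cells that hold these transcripts are not known and fat-cell formation itself was not measured. In this list 1 gene was at least 1.5-fold higher and 1 at least 1.5-fold lower. The higher gene was cebpb, an early regulator of fat-cell differentiation, with 19.2 and 30.7 FPKM and a read ratio of 1.59 (1.43 to 1.76). The lower gene was lpin1, a phosphatidate phosphatase of triglyceride synthesis, with 22.7 and 12.2 FPKM and a read ratio of 0.649 (0.596 to 0.706). The glycerol-3-phosphate dehydrogenase gene gpd1a had a read ratio of 1.46 (1.2 to 1.79) and the fatty acid synthase gene fasn 0.728 (0.660 to 0.802). For pparg, the central regulator of fat-cell formation, 64 and 91 reads gave a ratio of 1.24 (0.888 to 1.73), so that a difference was not detectable at this depth. The read ratio was 0.86 (0.777 to 0.952) for cebpa, 0.981 (0.913 to 1.05) for the fatty acid binding protein gene fabp11a and 0.938 (0.872 to 1.01) for the lipoprotein lipase gene lpl.

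The osteoblast list, genes of bone-forming cells, had a median difference of -0.03 over 31 measured genes, at percentile 8.43. It was lower on some other scales, with -0.08 at percentile 2.5 by reads, -0.06 at percentile 1.2 by FPKM without a minimum of reads, -0.06 at percentile 0.8 with 5 CPM (counts scaled to library size) added and -0.16 at percentile 0 with 1 CPM added and no minimum. In this list 1 gene was at least 1.5-fold higher and 5 at least 1.5-fold lower. The lower genes included col10a1a, a collagen of bone-forming and hypertrophic cartilage cells, with 101 and 37.5 FPKM and a read ratio of 0.367 (0.350 to 0.385), the channel gene panx3 at 0.304 (0.201 to 0.451), entpd5a, which is needed for mineralization, at 0.566 (0.473 to 0.676), and the osteoblast gene ifitm5, named after its value was seen, at 0.551 (0.388 to 0.776). The fibril-associated collagen gene col12a1a had a read ratio of 0.741 (0.720 to 0.764). The fifth, the bone collagen gene col1a1a, had 701 and 436 FPKM and a read ratio of 0.787 (0.779 to 0.796), so that its FPKM values are further apart than its reads. The higher gene was twist1b, named after its value was seen, with 9.54 and 15.8 FPKM and a read ratio of 1.53 (1.3 to 1.82). The osteoblast regulators were too shallow for a difference to be detectable, with 11 and 8 reads for runx2a (0.632, 0.221 to 1.73) and 45 and 43 reads for runx2b (0.831, 0.534 to 1.3), as was spp1 with 27 and 37 reads (1.19, 0.706 to 2.03). The genes sp7 and bglap were not analysed here.

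Cartilage genes were lower as a group. Of 28 measured genes of the chondrocyte list, 16 were at least 1.5-fold lower and 0 at least 1.5-fold higher, and the median difference of -0.66 was at percentile 0. The cartilage proteoglycan gene acana had 31.0 and 5.69 FPKM and a read ratio of 0.186 (0.168 to 0.206), fgfbp2b 0.293 (0.268 to 0.319) and the cartilage collagen gene col9a1a 0.318 (0.305 to 0.331). The main cartilage collagen gene, col2a1a, had 664 and 366 FPKM and a read ratio of 0.543 (0.537 to 0.548). The transcription factor gene sox9a, which directs cartilage formation, was closer to 1, at 0.859 (0.768 to 0.962). Across the collagen family 12 of 53 genes were at least 1.5-fold lower and 0 higher, with a median of -0.10 at percentile 0.01, and col8a2 had a read ratio of 0.437 (0.401 to 0.476) and col5a2b 0.339 (0.271 to 0.422). Genes of the fin fold and connective tissue had a median of -0.29 over 35 genes (percentile 0), with 4 at least 1.5-fold lower. Among them were the actinodin genes and2 and and1, structural proteins of the fin fold, with read ratios of 0.374 (0.362 to 0.386) and 0.553 (0.534 to 0.573), the tendon gene tnmd at 0.602 (0.501 to 0.722) and the matrix proteoglycan gene prelp at 0.506 (0.403 to 0.632).

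**Figure D3:**
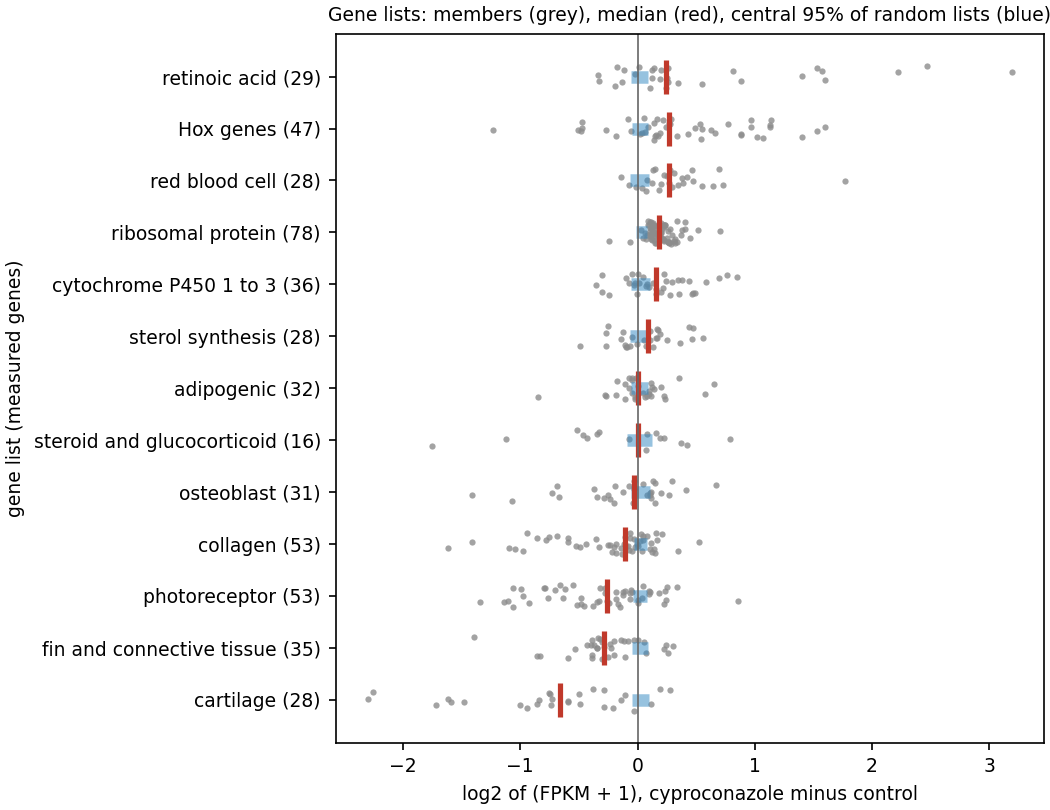
Differences in log2(FPKM + 1), cyproconazole minus control, for the members of 13 gene lists; the number of measured genes follows each list's name. Grey points are genes, red marks are list medians and blue bars span the central 95% of medians of random lists matched on expression. The retinoic acid and Hox medians lie at 0.24 and 0.27, the cartilage median at -0.66 and the adipogenic median at 0.00.

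Among genes of drug metabolism, the cytochrome P450 families 1 to 3 had a median difference of 0.16 over 36 genes (percentile 99.9), with 3 at least 1.5-fold higher and 0 lower. By reads, 9 were at least 1.5-fold higher and 1 lower, which was cyp2r1 at 0.606 (0.459 to 0.797), named after its value was seen. The read ratio was 2.18 (1.67 to 2.89) for cyp3a65, 1.82 (1.66 to 2.0) for cyp2aa8 and 1.54 (1.43 to 1.66) for cyp2ad3, and these gene families can share reads among close paralogs. The sulfotransferase genes had a median of -0.15 over 11 genes (percentile 1.54) but 0.07 (percentile 70.4) with at least 200 reads and -0.01 (percentile 38.8) without a minimum, and sult3st3 had a read ratio of 0.313 (0.194 to 0.492). The targets of the xenobiotic receptors had a median of 0.00 over 60 genes (percentile 27.9), with 3 at least 1.5-fold higher and 0 lower. By reads, 7 of these targets were at least 1.5-fold higher and 3 lower. The genes cyp3a65, cyp2aa8 and cyp2ad3 are on this list too. Targets of the aryl hydrocarbon receptor had a median of 0.04 over 9 genes (percentile 62.2), but 0.23 (percentile 99.7) with at least 200 reads, and 5 of the 9 were above 0 and 4 below. The standard marker of that receptor, cyp1a, had a read ratio of 0.702 (0.520 to 0.945), and cyp1b1, named after its value was seen, had 0.726 (0.534 to 0.985). The ratio was 1.32 (1.16 to 1.5) for cyp1c1, 1.6 (1.34 to 1.92) for foxq1a and 1.26 (1.13 to 1.41) for tiparp. In the list of the sterol pathway, which triazole fungicides inhibit in fungi, the median was 0.09 over 28 genes (percentile 93.1) and 0 genes passed 1.5-fold in either direction. Here cyp51, the lanosterol demethylase that triazoles target in fungi, had a read ratio of 1.0 (0.859 to 1.17), sqlea 1.46 (1.11 to 1.94), srebf2 1.38 (1.27 to 1.49) and hmgcs1 0.796 (0.728 to 0.87). For hmgcs1 the FPKM went the other way, with 20.45 in the control and 22.1 in the cyproconazole library.

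The list of steroid synthesis and glucocorticoid response had a median of 0.00 over 16 genes (percentile 39.4), with 1 gene at least 1.5-fold higher and 2 lower, or 2 higher and 5 lower by reads. This median depended on the minimum: it was -0.20 (percentile 0) for genes with at least 1 FPKM, -0.33 (percentile 0) with at least 200 reads and 0.08 (percentile 94.2) without a minimum. The glucocorticoid-responsive genes fkbp5 and klf9 had 2021 and 638 reads and 527 and 252 reads in the control and the cyproconazole library, with read ratios of 0.274 (0.251 to 0.3) and 0.416 (0.356 to 0.484), and the gluconeogenic gene pck1 had 0.654 (0.603 to 0.709). The cholesterol transporter gene star, which supplies steroid synthesis, was at 1.91 (1.49 to 2.46).

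Among the tissue markers, photoreceptor genes were lower and red blood cell genes higher. In the photoreceptor list 15 of 53 genes were at least 1.5-fold lower and 1 higher, with a median of -0.26 (percentile 0). The cone genes opn1mw1, pde6c and opn1sw2 had read ratios of 0.386 (0.363 to 0.409), 0.409 (0.373 to 0.449) and 0.461 (0.434 to 0.490), and prph2b had 0.442 (0.391 to 0.5). The higher gene was the retinol acyltransferase gene lrata, at 1.98 (1.55 to 2.53), and the rod opsin gene rho was at 1.17 (1.11 to 1.24), both named after their values were seen. In the red blood cell list 4 of 28 genes (hbbe3, gata1a, slc4a1a and, named after its value was seen, zgc:163057) were at least 1.5-fold higher and 0 lower, with a median of 0.27 (percentile 100), and gata1a, slc4a1a and alas2 had read ratios of 2.11 (1.34 to 3.41), 1.70 (1.56 to 1.85) and 1.5 (1.4 to 1.61). Ribosomal protein genes had a median of 0.18 over 78 genes (percentile 100), and 76 of them were above 0. The random lists were not matched on transcript length, and an effect of length was not tested for the lists of this paragraph. Pigment cell genes of the melanophore list had a median of 0.01 over 14 genes (percentile 44.7), and mitfa had a read ratio of 1.2 (0.945 to 1.53). Of all 61 lists and families with at least 3 measured genes, 14 had a median above the central 95% of their random lists, 12 below it and 35 within it.

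By recovered reads, 106 genes were at least 2-fold higher and 166 at least 2-fold lower, and 19 and 73 when the interval bound nearest to 1 had to pass 2-fold.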

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

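No paired analysis was possible because each group has 1 library, and for the same reason no library can be left out in turn. The recovered-read values on their own scaling, the other values added to FPKM, the centring on the median gene and the FPKM filters were chosen after the data were seen. The planned scalings were run on recovered reads, whose use was also chosen then. Against 50 genes at least 2-fold higher and 83 lower on log2(FPKM + 1), the counts by recovered reads were 106 and 166 with a trimmed mean of M values, 106 and 169 with the deposited size factors, 108 and 165 with total counts, 106 and 169 with upper-quartile factors and 106 and 166 with a library size that leaves out mitochondrial and the 50 most abundant genes. Adding 0.1 in place of 1 to each FPKM gave 125 and 162, which by construction raises the ratios of low genes. Adding 5 CPM (counts scaled to library size) gave 12 and 40, a 1.5-fold threshold 295 and 318, at least 200 reads 30 higher, and an interval bound past 2-fold 19 higher. All of these keep more genes lower than higher. Of the lists, 26 lay outside the central 95% of random lists, 24 to 36 under the alternatives, and 0 moved from one side to the other. Of the 26, 20 stayed outside on the same side with at least 200 reads and 23 to 26 under the other alternatives. The adipogenic median stayed within its counting error under every alternative run. The osteoblast median was -0.16 with 1 CPM added and no minimum, and -0.18 for the summed reads of the list, in which abundant collagens weigh most; beyond that the cause was not tested. Among the lists outside the central 95%, medians changed sign with at least 200 reads for the endocrine (-0.0126), myeloid (0.0149) and sulfotransferase lists (0.0667), and for summed reads for the intestine (0.0707), myeloid (0.0824) and later larval lists (0.0292); the cause was not tested. Some lists within the central 95% changed sign too, such as the steroid and glucocorticoid list (-0.33 with at least 200 reads). Besides the 6 changes of sign in lists outside the central 95%, 77 list medians under alternatives moved by more than their counting error, and 710 did not. Among the values of 110 named genes under alternatives, 176 moved by more than their counting error and 698 did not. Of these genes, dio1 is the one past 1.5-fold whose sign changed. Its log2 ratio was -0.63 to -0.62 by reads (-0.26 with 5 CPM added) and positive by FPKM; the cause was not tested. Depth limits genes with few reads: the interval of pparg spans 0.888 to 1.73.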

Other observations

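The tests of transcript length and abundance, of late larval genes and of the circadian list were chosen only after the result was seen; those on the 2 further gene lists were written before their values were seen. Other organ and cell lists also lay off the random lists. The exocrine pancreas list had a median difference of -0.18 over 11 genes (percentile 0.62), with read ratios of 0.395 (0.301 to 0.513) for the chymotrypsinogen gene ctrb1 and 0.493 (0.385 to 0.629) for the trypsin gene prss59.2. The intestine list had -0.10 over 17 genes (percentile 1.69; 22.6 with at least 200 reads), with the apolipoprotein gene apoa4a at 0.286 (0.203 to 0.396), though the summed reads of the intestine list were higher (log2 0.0707). Myeloid and inflammatory genes had a median of -0.11 over 26 genes (percentile 0.41), with the chemokine gene ccl34b.1 at 0.273 (0.145 to 0.486), a median of 0.0149 with at least 200 reads, and the gene irg1l at 0.624 (0.537 to 0.724), while the cytokine-signalling inhibitor socs3b was at 1.71 (1.49 to 1.98). Neuron genes had a median of -0.08 over 43 genes (percentile 0.09), with the GABA-synthesis genes gad1b and gad2 at 0.769 (0.723 to 0.819) and 0.792 (0.751 to 0.835). Of these neuron genes 0 were at least 1.5-fold lower and 1 was higher, dbh at 1.65 (1.21 to 2.25).

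Higher lists were those of the hatching gland and early embryo, with a median of 0.38 over 11 genes (percentile 100; 0.24 at percentile 99 by reads, and 0.07 at percentile 86.5, within the central 95%, with 5 CPM added) and the hatching enzyme gene he1a at 1.67 (1.28 to 2.19), of endocrine cells, with 0.23 over 24 genes (percentile 99.99; -0.0126 with at least 200 reads) and the pituitary hormone gene smtlb at 2.38 (1.78 to 3.22) against the thyroglobulin gene tg at 0.478 (0.406 to 0.561), of muscle regulators, with 0.16 over 14 genes (percentile 98.6) and the fusion gene mymx at 1.73 (1.34 to 2.24; the median was at percentile 92.2 with at least 200 reads), and of the epidermis, with 0.12 over 43 genes (percentile 99.96). Of the epidermis genes, the keratin gene krt94 was at 1.52 (1.4 to 1.65), but muc5.2 at 0.308 (0.271 to 0.35) and evplb at 0.722 (0.687 to 0.758), and the keratin family alone had a median of 0.04 over 18 genes (percentile 61.0). Cell cycle genes had a median of 0.10 over 46 genes (percentile 99.5), and 0 of them passed 1.5-fold. Lens genes had a median of 0.03 over 43 genes (percentile 56.1) and fast muscle genes -0.03 over 37 (percentile 4.21). The same 37 fast muscle genes had a median log2 read ratio of -0.04. Over all fast muscle genes with at least 50 reads, whatever their FPKM, the read median was -0.07 at percentile 0.1.

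The higher retinoic acid responsive and anterior Hox genes may reflect raised retinoic acid signalling, since azoles can inhibit the cytochrome P450 enzymes that break down retinoic acid. A further list of 19 genes reported to respond to retinoic acid, none on the fixed lists, had 17 measured, 15 of them above 0, and a median log2 read ratio of 0.24, at percentile 100 of matched random lists. This list held 1 gene at least 1.5-fold higher and 0 lower, and several of its members are paralogs, such as the meis genes, which need not vary separately. Its highest member was meis1a at 1.6 (1.46 to 1.75), meis3 was at 1.39 (1.27 to 1.53), and the 2 below 1 were nr2f1b at 0.958 (0.811 to 1.13) and tshz1 at 0.986 (0.922 to 1.05), all 4 named after their values were seen. Removing the trends on transcript length (reads per FPKM as a stand-in) and abundance left the median of Hox groups 1 to 8 at 0.88 (0.56 to 1.1, resampled genes) against 0.94 before, which argues against such a bias as the whole cause. Retinoic acid was not measured, and a shift in developmental stage stays open for this pattern as well.

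For the lower cartilage matrix genes, the same trend removal left the list median at -0.66 (-1.01 to -0.38) against -0.69, which argues against transcript length or abundance as the whole cause. A developmental delay of the treated pool could also lower genes that rise late. The later larval list had a median log2 read ratio of -0.18 and the hatching gland and early embryo list was higher, both of which go with a delay. The summed reads of the later larval list, however, were not lower (log2 0.0292). Its member rho, at 1.17 (1.11 to 1.24), is part of that sum, so these values are not separate counterpoints. Other lists off the random lists, such as the photoreceptor, exocrine pancreas and cell cycle lists, were not weighed for a delay. With 1 age sampled a delay and a change at the same stage cannot be told apart.

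The lower glucocorticoid responsive genes fkbp5, klf9 and pck1, beside higher star, may reflect lower glucocorticoid signalling. A further list of 22 genes reported to respond to glucocorticoids had 16 measured and a median log2 read ratio of -0.02 at percentile 32.3, with 8 above 0, so it met neither bound set beforehand and leaves this open. A different hour of collection is a candidate explanation too: the median absolute log2 read ratio of the 39 measured circadian genes was 0.19, at percentile 99.6, with nr1d1 at 0.539 (0.439 to 0.659) and per1a at 0.561 (0.435 to 0.723). Another gene of the list, aanat2, was higher at 2.34 (1.47 to 3.83), and per1b, named after its value was seen, was at 1.01 (0.937 to 1.09). An absolute ratio has no direction and was taken for no other list, so this value cannot tell the hour of collection from another cause. The hour of collection is not given in the sources used here.

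Few of the genes with a conventional symbol furthest from a ratio of 1 stand near the top by the deposited p-value. Of these 24 genes, 1 (hbbe3) has a p-value under 0.05 in the authors' deposited table, and cyp26a1 stands at rank 2890 there with a p-value of 0.342 and a log2 ratio of 0.04. The dispersion that gives the deposited ratio in the authors' deposited table was 1.49 for cyp26a1 and 0.908 for matn1, against a median of 0.0095 over 3678 genes with a mean count above 1000. With 1 library per group, no spread within a group could enter these dispersions. They and the deposited p-values therefore do not show that the genes furthest from 1 are noisy. For dio1, a deiodinase gene also named after its value was seen, 74.3 and 508 FPKM stood beside a read ratio of 0.649 (0.460 to 0.913).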
